A study of Drosophila melanogaster with 12 samples.

How the data were processed

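The samples were pools of 20 larval fat bodies of Drosophila melanogaster, hybridised to Affymetrix whole-genome arrays, 12 arrays in 4 groups of 3. Per the labels, 30 ng of total RNA per sample went through reverse transcription and biotin labelling with a protocol of 2 amplification rounds, and only RNA within set quality ratios was used. Groups and replicate numbers were taken from the sample titles. The design text calls the samples biological replicates. It does not say whether a shared replicate number links samples of different groups, so no block was used. The age of 4 days in the wildtype and 5 days in the mutant comes from the sample characteristics, while the extraction text gives mutant larvae of 5 days for every sample.

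The authors deposited 1 table of linear intensity values per probe set and array, made with GCOS 1.4 and MAS5 per the submitters' processing notes. MAS5 summarises a probe set into a background-corrected signal and scales each array so that its trimmed mean equals a target. The deposited intensity values had the same trimmed mean on every array (500.02 to 500.03) after leaving out the top and bottom ends, so they were taken as scaled, and no further normalization was applied. Such scaling fixes the average of each array, so that a change of total messenger RNA per cell would not be seen. All 12 columns belonged to a sample. The detection calls that such software makes were not used here. Arrays give no read depth, and their number limits the precision.

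The array held 18952 probe sets, of which 183 controls were left out. Of the other 18769, 13646 had 1 gene symbol in the platform annotation, 402 had several and 4721 had none. Through gene identifiers 13543 matched the RefSeq gene table of the organism, with 0 changed symbols, and 103 kept the platform's name, which gave 11981 genes in all. No gene was named from a probe set with several symbols, and probe sets without a symbol are unnamed here. No probe set was named srl, w or Thor in the annotation used, so these genes were not analysed here.

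Values were transformed as log2(value + 16), and the lowest 40% of probe sets by mean over all arrays were left out, which left 11261. A fold change is on this log2(value + 16) scale and understates the change of low genes. One linear model with a coefficient per group was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), so that the groups share 1 estimate of the spread with 8 residual degrees of freedom. It gave 5 comparisons: the Inr effect in each background, the mutant effect without and with Inr, and the difference between the Inr effects (interaction). Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05 on the adjusted p. Adjusted p-values in the text come from this fit unless camera or fry is named. Errors beside log2 changes are standard errors of the fit. The shared response was counted per direction against independent lists with Fisher's exact test. Response size was taken over probe sets that passed for the mean of both Inr effects, which is independent of their difference, with fry as the test.

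There were 39 gene lists, 26 of pathways, 11 of markers of other tissues that a dissection can carry along, and 2 of check genes. They were compiled from general knowledge of the fly, and the pathway and tissue lists with at least 5 tested genes (26 and 10) were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, the one with the highest mean. The Benjamini-Hochberg adjustment ran over the lists of one kind within a comparison. In the text a list's adjusted p is that of camera, and genes counted as higher or lower are those past the threshold over all probe sets tested. The count adjusted over the list alone stands beside it. Camera with an estimated correlation and fry were run as well.

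Named genes followed a rule. InR came first. Then came, in each comparison, the 10 genes with the largest rise and the 10 with the largest fall among probe sets with 1 symbol that passed and whose 3 and 3 arrays did not overlap (for the interaction: that passed), with 1 probe set per gene. For each list up to 2 members with the smallest p were named per direction. Genes with only a CG symbol may be counted without being described. The marker gene y is given because fly stocks carry such markers. The groups, comparisons, tests, gene lists, alternatives and this rule were fixed before the data were examined.

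The fit was tested on simulated data for all 11261 probe sets, in which 67 were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For the Inr effect in the wildtype 8, 32 and 51 of them were recovered, with 4 false calls. For the Inr effect in the mutant the numbers were 17, 39 and 50, with 7 false calls. For mutant against wildtype controls they were 11, 35 and 59, with 4 false calls, and for the mutant effect with Inr 6, 26 and 58, with 7 false calls. For the interaction 1, 16 and 38 were recovered, with 2 false calls. Changes of 1.5-fold in single genes were thus mostly missed in this simulation, in the interaction above all. It gave 57 to 113 calls per comparison, against 1113 to 3827 in the data. With so few calls the adjustment is stricter, so recovery in the data can be higher than these numbers. A simulated shift of 0.5 in the ribosome biogenesis list was recovered, with 0 of 36 other lists called. The simulated genes varied independently, so this could not test how correlation between genes affects the list calls.

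Alternatives changed one choice at a time: a pseudocount of 1 or 64, no filter or a filter on the lowest 60%, quantile normalization or centring each array on its median, eBayes without the trend, only the compared groups in the fit, array quality weights, a minimum change of 2-fold, the replicate number as a block, leaving out each array in turn, and for lists the mean of all probe sets of a gene. After the data were seen, fits without mutant control replicate 1 and wildtype control replicate 3, which stood apart in tissue markers, and with the mean of the muscle markers as a covariate were added, as was, for the respiratory chain genes in the Inr effect of the mutant and in the interaction, the 3' to 5' signal ratio as a covariate. Neighbour relations and chromosomes of genes came from the RefSeq table and were used for 4 tests in the closing section. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.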

Results

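Messenger RNA levels were measured in the larval fat body of Drosophila melanogaster, the organ that stores fat and glycogen and secretes most blood proteins. The study asked whether the transcriptional response to insulin signalling depends on spargel (srl), the fly homologue of the PGC-1 family of transcriptional coactivators that act on mitochondrial genes. There were 12 arrays in 4 groups of 3 biological replicates. Wildtype larvae without and with overexpression of the insulin receptor (InR) are called wildtype controls and wildtype Inr larvae. Larvae homozygous for the srl1 allele are called mutant controls and mutant Inr larvae. All 12 samples, controls included, had a heat shock of 30 min at 37 °C, given 13 h before dissection. In the Inr groups it switched on the UAS-Inr transgene. Wildtype larvae were 4 days old and mutant larvae 5 days old after egg deposition, so that age and genotype changed together and cannot be separated. Each sample pooled 20 fat bodies. The deposited array signals had the same trimmed mean on every array (500.02 to 500.03), while their medians ran from 37.6 to 55.0.

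The arrays fell into their 4 groups. The first principal component of the log2 values took 43.6% of the variance and the second 17.1%. On the first, mutant controls lay at -75.0 to -65.3, wildtype controls at -12.1 to -9.84, mutant Inr arrays at 21.5 to 30.3 and wildtype Inr arrays at 51.5 to 56.2. The second set wildtype controls (-50.6 to -48.8) apart from mutant controls (20.8 to 22.0). Correlations between arrays of one group were 0.947 to 0.976, and those between groups 0.848 to 0.957.

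**Figure D1:**
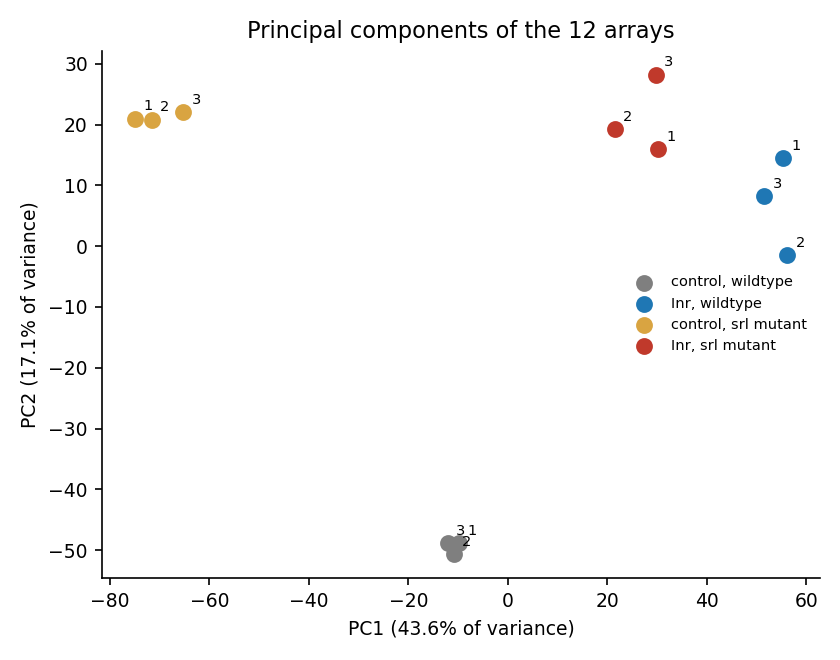
Scores of the 12 arrays on the first (x axis) and second (y axis) principal components of the log2 values of 11261 probe sets, each point an array and each colour a group. The first component takes 43.6% of the variance and puts mutant controls at one end (-75.0 to -65.3) and wildtype Inr arrays at the other (51.5 to 56.2).

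The overexpressed gene itself followed the labels. InR had a mean log2 level of 7.97 ± 0.25 (SD, n = 3) in wildtype controls and 14.51 ± 0.15 in wildtype Inr larvae, and of 8.86 ± 0.42 in mutant controls and 14.53 ± 0.07 in mutant Inr larvae. The rise was 93.3-fold in the wildtype (log2 change 6.54 ± 0.19 SE, adjusted p = 4.64e-10, limma with Benjamini-Hochberg adjustment) and 50.8-fold in the mutant (5.67 ± 0.19 SE, adjusted p = 2.43e-09). Levels under overexpression differed by 0.02 between the backgrounds (adjusted p = 0.976), and the smaller fold came with a higher InR level in mutant than in wildtype controls (0.89 ± 0.19 SE, adjusted p = 0.00265). The difference between both responses was -0.88 ± 0.26 SE (adjusted p = 0.0499), and it no longer passed when any 1 of 10 arrays was left out, that is any but wildtype control replicate 3 and mutant control replicate 1 (adjusted p 0.0567 to 0.122). The probe set does not separate transgene from endogenous InR. The marker gene yellow (y) changed in no comparison, with values from -0.37 for the difference of responses (adjusted p = 0.858) to 1.21 in mutant against wildtype controls (adjusted p = 0.151). Without mutant control replicate 1 the latter was 1.88 (adjusted p = 0.0181). The srl transcript was not analysed here.

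The first comparison asked what InR overexpression did in wildtype fat body. Of 49 tested ribosome biogenesis genes 42 rose and 1 fell, with a median log2 change of 1.17, and 20 of 29 DNA replication and 34 of 71 mitochondrial ribosomal protein genes rose. These lists passed camera, but not with an estimated correlation (adjusted p = 0.302, 0.488 and 0.488). Of the autophagy list 7 of 22 genes fell and of the ecdysone list 7 of 20 (adjusted p = 0.302 and 0.436 with an estimated correlation). The stress-induced Turandot genes TotF, TotE and TotC were among the largest rises and Sgs glue genes among the largest falls. The secreted Turandot peptides TotF and TotE rose by 8.15 ± 0.39 SE and 8.08 ± 0.63 SE on the log2 scale (n = 3 arrays per group).

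In this comparison 2921 of 11261 probe sets passed (25.9%), 1552 higher and 1369 lower, by limma with Benjamini-Hochberg adjustment. With each array centred on its median, which moved the median of all genes by -0.13, 3119 passed and 39.4% of them were higher, against 53.1% as deposited. Signals of all 3 arrays of one group lay above all 3 of the other for 4555 probe sets, where chance gives 10%. The largest rises among named genes were InR, 5 genes with only a CG symbol led by CG43133 (8.71), TotF (adjusted p = 5.06e-08), TotE (1.81e-06), TotC (6.15 ± 0.32 SE, 7.1e-08), and the odorant-binding protein gene Obp83cd (5.69 ± 0.36 SE, 3.17e-07). The largest falls were in the salivary glue genes Sgs3 (-8.46 ± 2.11 SE, adjusted p = 0.00959) and Sgs1 (-8.10 ± 1.59 SE, 0.00215), followed by Sgs7 (-7.36), Sgs4 (-7.35), Sgs5bis (-7.04) and Sgs8 (-6.46). The lysozyme gene LysS fell by 6.85 (adjusted p = 0.00598), NimC2, a Nimrod receptor of phagocytic blood cells, by 6.59 ± 0.81 SE (6.52e-05), CG34279 by 5.97 and the ecdysone-induced gene Eig71Ee by 5.96 (0.0183). Sgs7 and Sgs8 no longer passed without any 1 of 5 arrays, wildtype control replicates 1 to 3 and wildtype Inr replicates 1 and 3 (adjusted p 0.0583 to 0.118 and 0.0561 to 0.105). Sgs4 was lost without wildtype control replicate 2 or wildtype Inr replicate 1 or 3 (0.0521 to 0.0669), and Eig71Ee without wildtype Inr replicate 1 or 3 (0.0661 to 0.0726). Sizes of these falls depended on single arrays of wildtype Inr larvae. Without replicate 2 the log2 change was -10.10 for Sgs3, -9.96 for Sgs7, -8.17 for Sgs4, -8.07 for Sgs5bis, -8.18 for Sgs8, -7.76 for LysS and -7.27 for Eig71Ee. Without replicate 1 it was -7.52 for Sgs3, -6.44 for Sgs5bis, -5.50 for Sgs8 and -5.26 for Eig71Ee, and without replicate 3 it was -5.85 for Sgs7. Without wildtype control replicate 3 it was -6.01 for LysS and -5.36 for CG34279.

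Among growth genes, the ribosome biogenesis list was the most shifted (camera adjusted p = 1.23e-17, adjusted p = 0.302 with an estimated correlation). Adjusted over the list alone, 44 rose and 1 fell. Examples were the pseudouridine synthase gene Nop60B (1.72) and bor (2.09), while NAT1, which encodes a translation factor related to eIF4G, fell by 0.52. Of 29 DNA replication and G1/S genes 20 rose, also adjusted over the list alone, and none fell (median 1.13, adjusted p = 1.33e-06). They included RnrL, the large subunit of ribonucleotide reductase (1.47), and the helicase component Cdc45 (1.82). Of 20 aminoacyl-tRNA synthetase genes 9 rose (10 higher and 1 lower adjusted over the list alone, median 0.30, adjusted p = 0.00266), such as IleRS (0.81) and LeuRS (0.78). With an estimated correlation the adjusted p was 0.488 for DNA replication and 0.436 for the synthetases.

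The lists of mitochondrial gene expression were higher by camera in the wildtype too. Of 71 mitochondrial ribosomal protein genes 34 rose and none fell (43 and 0 adjusted over the list alone, median 0.44, adjusted p = 3.45e-09, adjusted p = 0.488 with an estimated correlation), with mRpL13 at 1.15 and mRpL4 at 0.97. Of 20 genes of mitochondrial transcription and import 9 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.31, adjusted p = 0.00293, adjusted p = 0.436 with an estimated correlation). The import pore gene Tom40 rose by 1.33 and the elongation factor gene mEFG1 by 1.79. Genes of the respiratory chain moved little. In complex I 7 of 27 rose and 1 fell, likewise adjusted over the list alone (median 0.27, adjusted p = 0.0155, adjusted p = 0.721 with an estimated correlation), with ND-SGDH at 0.67 and ND-MNLL at 0.49, and centring each array on its median ended this shift (adjusted p = 0.0914), as did fry (adjusted p = 0.0706). The lists of complexes II and III, IV and V did not pass (adjusted p = 0.159, 0.778 and 0.171), with 1, 0 and 0 members higher. Their mean log2 levels were 11.95, 12.93 and 13.42 in wildtype controls and 12.15, 12.92 and 13.21 in wildtype Inr larvae, so that complex V was lower on average.

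Of 22 autophagy and lysosome genes 7 fell and 2 rose (8 and 2 adjusted over the list alone, median -0.22, adjusted p = 0.0203, adjusted p = 0.302 with an estimated correlation). The autophagy kinase gene Atg1 fell by 1.32 and Atg18a by 0.82, while the cathepsin gene CtsL1 rose by 2.33. Of 26 proteasome genes 10 fell (12 adjusted over the list alone, median -0.26, adjusted p = 0.000127), such as the regulatory lid subunits Rpn11 (-0.48) and Rpn5 (-0.50). Of 20 juvenile hormone and ecdysone genes 7 fell, also adjusted over the list alone (median -0.47, adjusted p = 0.0203), among them the ecdysone receptor EcR (-1.41) and br (-2.06). Of 18 genes of beta-oxidation and ketone bodies 8 fell and 2 rose, likewise adjusted over the list alone (median -0.28, adjusted p = 0.0239). The thiolase gene yip2 fell by 0.89 and the acyl-CoA oxidase gene Acox3 by 1.44, while Had1 rose by 2.10. With an estimated correlation the adjusted p was 0.488 for the proteasome, 0.436 for the ecdysone list and 0.565 for beta-oxidation. The beta-oxidation list did not pass without wildtype control replicate 1 or 2 (adjusted p = 0.0628 and 0.0508).

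Further lists passed with few members. The unfolded protein response and ER list had 4 of 16 lower, also adjusted over the list alone (median -0.27, adjusted p = 0.0155), including sordd1 (-0.64), and ended without wildtype Inr replicate 3 (0.0581). The storage protein list had 2 of 8 lower, also adjusted over the list alone, Fbp1 (-1.14) and Obp99a (-1.46) (median -0.47, adjusted p = 0.0275). It ended without wildtype Inr replicate 3 (0.0745), with quantile normalization (0.0696) and with centring (0.0531). The adjusted p was 0.488 with an estimated correlation for both. The cytosolic ribosomal protein list was lower in its median (-0.25, adjusted p = 0.0324, adjusted p = 0.752 with an estimated correlation), but 3 of its 39 genes rose, such as RpL24-like (0.99), and 1 fell, 3 and 0 adjusted over the list alone. Its direction turned with quantile normalization (median 0.02, adjusted p = 0.624), and it ended without wildtype control replicate 2 (0.171) or wildtype Inr replicate 1 or 3 (0.15 and 0.166), without a filter (0.0896), with the mean of all probe sets of a gene (0.103) and by fry (adjusted p = 0.298). Of 18 immune effector genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.98, adjusted p = 0.0135, adjusted p = 0.488 with an estimated correlation), TotC and the peptidoglycan receptor gene PGRP-SB1 (2.18) among them.

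The insulin, glycolysis and fatty acid lists did not pass, though single members changed. The insulin and FOXO linked list had 3 higher and 6 lower (adjusted p = 0.945). The alpha-glucosidase gene tobi, a known target of insulin-producing cells, rose by 4.22, whereas foxo itself fell by 0.86 and the lipase gene bmm by 1.24. In glycolysis and glycogen 5 rose and 4 fell (adjusted p = 0.536), with the hexokinase gene Hex-C at 4.90 and the glycogen synthase gene Glys at 1.20. In the fatty acid list 3 rose and 3 fell (adjusted p = 0.778), with the lipid carrier gene Apoltp at 1.79 and the lipid droplet gene Lsd-1 at -0.87. The amino acid transporter genes mnd and JhI-21 rose by 2.75 and 1.35. Among markers of other tissues, 8 of 12 salivary gland genes fell and 2 rose, the new glue genes ng2 (4.39) and ng3 (3.19) (median -5.61, adjusted p = 0.474), and no tissue list passed. The rise of ng3 was lost when any 1 of 9 arrays was left out, all but wildtype control replicate 3 and mutant control replicates 1 and 3 (adjusted p 0.0614 to 0.15). Without wildtype control replicate 3 the rise was 5.29 for ng2 and 3.95 for ng3.

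**Figure D2:**
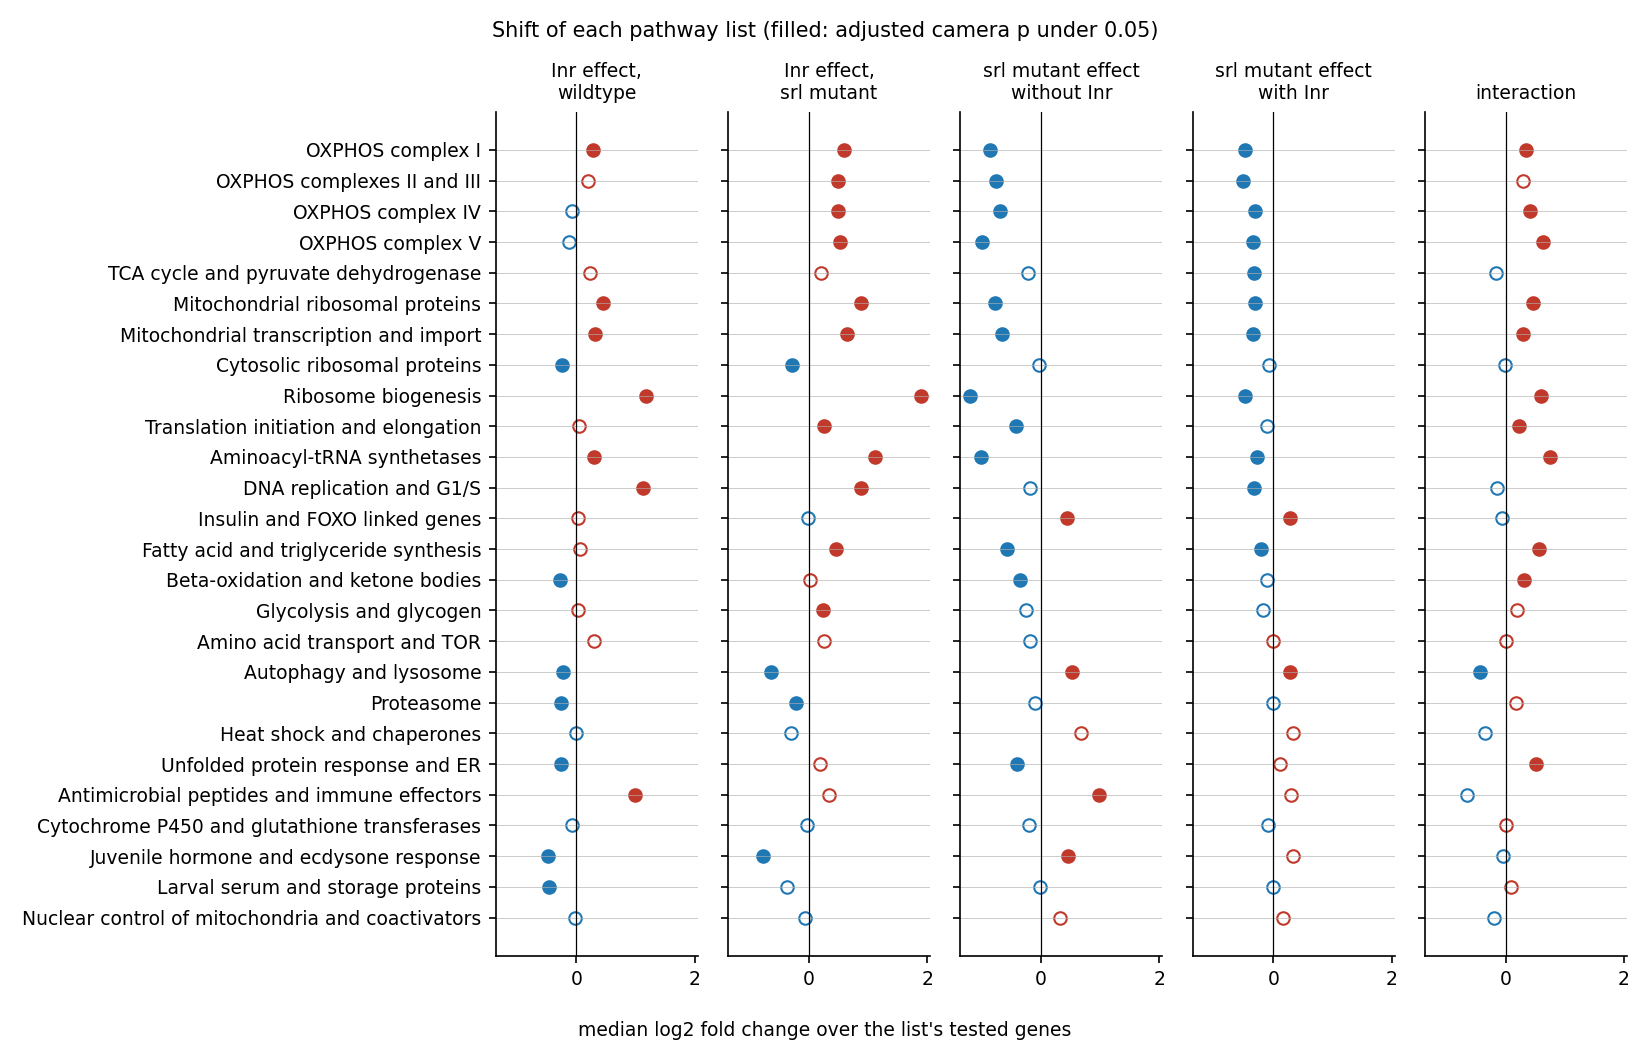
Median log2 fold change over the tested genes (x axis) of each of 26 pathway lists (y axis), in 1 panel per comparison, with red points above and blue points below 0, filled where the list passed camera at an adjusted p under 0.05. Ribosome biogenesis had a median of 1.17 and 1.89 for both Inr effects and of -1.21 in mutant against wildtype controls.

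In the spargel mutant the same overexpression asked which part of the response is seen in larvae homozygous for srl1. Of 49 ribosome biogenesis genes 45 rose (median 1.89), and of 71 mitochondrial ribosomal protein genes 62 rose (median 0.89). The aminoacyl-tRNA synthetase list and the 4 lists of the respiratory chain were higher by camera too, and the autophagy and ecdysone lists lower. Of these, autophagy passed with an estimated correlation (adjusted p = 0.037), and the respiratory chain lists did not (0.435 to 0.501). The Turandot genes TotF and TotE rose by 7.84 and 6.79 (n = 3 arrays per group).

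By limma with Benjamini-Hochberg adjustment 3827 of 11261 probe sets passed (34.0%), 2036 higher and 1791 lower. With each array centred on its median, which moved the median of all genes by -0.14, 3942 passed and 41.96% were higher, against 53.2% as deposited. The arrays of both groups did not overlap for 5139 probe sets, where chance gives 10%. The largest rise was in lectin-24A, a C-type lectin gene (8.11 ± 0.29 SE, adjusted p = 3.13e-09). It was followed by TotF, the Jonah protease gene Jon65Aii (7.55 ± 0.41 SE, 6.44e-08), CG43133 (7.40), ng2 (7.22 ± 0.97 SE), ng1 (7.04 ± 1.28 SE), CG18649 (6.88), TotE, TotB (6.74 ± 0.27 SE) and ng3 (6.37 ± 1.10 SE). The largest falls were in the drosomycin-like peptide gene Drsl5 (-6.53 ± 0.61 SE, 3.54e-06) and NimC2 (-6.35 ± 0.81 SE). The list also held hll (-5.34), the immunoglobulin-domain gene Ama (-5.04), the ubiquitin ligase gene gol (-4.85) and 5 genes with only a CG symbol, from CG8112 (-5.84) to CG6012 (-4.49). Single mutant controls set the size of several rises. Without mutant control replicate 1 the log2 change was 5.56 for ng1, 6.10 for ng2, 4.81 for ng3, 5.78 for CG18649 and 6.14 for TotE. Without mutant control replicate 3 it was 9.04 for ng1, 8.53 for ng2, 7.86 for ng3 and 7.98 for CG18649, and without mutant control replicate 2 it was 7.87 for TotE. Without mutant Inr replicate 2 it was -7.52 for Drsl5, -7.66 for NimC2, -6.50 for hll, -5.96 for Ama and -6.56 for CG8112. Without mutant Inr replicate 3 it was -4.63 for hll and -5.01 for CG8112, and without mutant Inr replicate 1 it was -5.60 for NimC2.

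The ribosome biogenesis list had 45 higher and 1 lower (46 and 1 adjusted over the list alone, adjusted p = 3.19e-22, adjusted p = 0.0809 with an estimated correlation), with Nop60B at 2.58, the snoRNP protein gene NHP2 at 2.60 and NAT1 at -0.88. Of 20 aminoacyl-tRNA synthetase genes 16 rose (17 adjusted over the list alone, median 1.12, adjusted p = 3.3e-09, adjusted p = 0.0694 with an estimated correlation), for example AlaRS (1.57) and SerRS (1.33). Of 29 DNA replication genes 17 rose (20 adjusted over the list alone, median 0.89, adjusted p = 0.000202, adjusted p = 0.501 with an estimated correlation), RnrL by 1.79 and Sld5 by 1.51. Of 39 translation factor genes 14 rose and 2 fell (16 and 2 adjusted over the list alone, median 0.25, adjusted p = 0.022, adjusted p = 0.583 with an estimated correlation), with eIF6 at 1.21 and eIF2beta at 0.87. That list ended with centring (0.112) and without mutant control replicate 2 (0.0579).

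Lists of mitochondrial gene expression and of the respiratory chain were higher, while those of the TCA cycle (4 higher, 2 lower, adjusted p = 0.452) and of beta-oxidation (5 higher, 6 lower, adjusted p = 0.812) did not pass. The mitochondrial ribosomal list had no member lower (64 higher adjusted over the list alone, adjusted p = 3.61e-18, adjusted p = 0.306 with an estimated correlation), with mRpL12 at 1.47 and mRpS26 at 1.46. In mitochondrial transcription and import 12 of 20 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.64, adjusted p = 3.91e-05, adjusted p = 0.171 with an estimated correlation). Tom40 rose by 2.39 and the chaperonin gene Hsp60A by 1.98, while ewg, the fly homologue of NRF-1, fell by 0.998. Complex I had 19 of 27 higher, also adjusted over the list alone (median 0.59, adjusted p = 1.48e-06), complexes II and III 8 of 10 (8 higher and 1 lower adjusted over the list alone, median 0.50, adjusted p = 0.00863), complex IV 8 of 12 (9 adjusted over the list alone, median 0.49, adjusted p = 0.00451) and complex V 11 of 13 (11 higher and 1 lower adjusted over the list alone, median 0.53, adjusted p = 0.00128). With an estimated correlation the adjusted p was 0.501, 0.501, 0.435 and 0.438 in that order. Examples were ND-SGDH (1.06), Cyt-c1 (1.19), COX5B (0.91) and ATPsyngamma (0.70). The groups also differed in a measure of RNA quality, the log2 ratio of 3' to 5' signal of the eIF-4a control probe sets, which was 1.77 to 1.95 in mutant controls and 1.39 to 1.65 in mutant Inr larvae. The mean log2 change of the 62 tested respiratory chain genes was 0.47 ± 0.07 SE by groups alone and 0.24 ± 0.08 SE with this ratio as a covariate, a fit chosen after the result was seen.

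Autophagy genes fell: 14 of 22 were lower and 1 higher (15 and 1 adjusted over the list alone, median -0.63, adjusted p = 3.91e-05), and the list also passed with an estimated correlation (adjusted p = 0.037). Atg1 fell by 2.33 and the cathepsin gene CtsB by 1.403, while Atg13 rose by 0.79. Of 20 juvenile hormone and ecdysone genes 10 fell and 1 rose, likewise adjusted over the list alone (median -0.77, adjusted p = 0.0022, adjusted p = 0.171 with an estimated correlation). The nuclear receptor gene Eip78C fell by 4.01 and the transporter gene E23 by 3.53, while ftz-f1 rose by 1.65. Of 26 proteasome genes 8 fell, also adjusted over the list alone (median -0.22, adjusted p = 0.0249, adjusted p = 0.59 with an estimated correlation), with Rpn5 at -0.52 and Rpt5 at -0.46. This list ended with quantile normalization (0.0864) and without mutant control replicate 3 (0.1) or mutant Inr replicate 2 (0.105). The cytosolic ribosomal list had a median of -0.28 (adjusted p = 0.0178, adjusted p = 0.659 with an estimated correlation) with 4 higher and 6 lower, 3 and 2 adjusted over the list alone, among them RpLP0-like (2.18) and RpS5b (-0.99). Its median was -0.03 after quantile normalization (adjusted p = 0.829), and it ended without mutant control replicate 1 (0.0738) or mutant Inr replicate 3 (0.119). It ended as well with the mean of all probe sets of a gene (0.0832), by fry (adjusted p = 0.185) and, in settings chosen after the data were seen, without both mutant control replicate 1 and wildtype control replicate 3 (0.0859) and with the muscle score as a covariate (0.197).

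Fat and sugar storage genes rose in part. In fatty acid and triglyceride synthesis 9 of 21 rose and 1 fell, likewise adjusted over the list alone (median 0.46, adjusted p = 0.0395, adjusted p = 0.59 with an estimated correlation). Acetyl-CoA carboxylase (ACC), which commits carbon to fatty acid synthesis, rose by 2.46, Apoltp by 2.59, and Lsd-1 fell by 1.13. In glycolysis and glycogen 5 of 17 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.24, adjusted p = 0.0345, adjusted p = 0.54 with an estimated correlation), with Hex-C at 5.35, Glys at 1.45 and Tpi at -0.38. The fatty acid list ended with centring (0.0509), with the stricter filter (0.0916) and without mutant control replicate 3 (0.102) or mutant Inr replicate 2 (0.105). The glycolysis list ended with centring (0.14), with the stricter filter (0.067) and without mutant control replicate 2 (0.0599) or mutant Inr replicate 1 (0.0581). The insulin and FOXO linked list did not pass (4 higher, 7 lower, adjusted p = 0.653), with foxo at -1.37, scyl at 1.48 and the activin-like ligand gene daw at -0.81. Amino acid transporter genes path (2.48) and JhI-21 (2.39) rose within a list of 5 higher and 3 lower (adjusted p = 0.452). No list of another tissue passed, with 3 higher and 0 lower for salivary gland (adjusted p = 0.132) and 2 higher for muscle (0.132).

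Both Inr responses shared many genes. The number higher in both backgrounds was 1058, where independent lists would share 281 (odds ratio 19.1, Fisher's exact test), and 863 were lower in both, against 218 (odds ratio 16.5). A further 103 passed in opposite directions. The 2 comparisons have no array in common. For response size, 4479 probe sets were taken by the mean of both Inr effects, a choice that favours neither background. Their median change in the direction of the mean effect was 0.62 in the wildtype and 0.81 in the mutant, a median gain of 0.21, and 64.8% responded more in the mutant. As a set they differed between the responses by limma's fry, a rotation test (n = 12 arrays, p = 0.00158). This held for genes that rose (2316 probe sets, 0.72 and 0.92) and those that fell (2163, 0.55 and 0.71).

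The effect of the spargel mutation without InR overexpression was read from mutant against wildtype controls, which also differ in age. The lists of all respiratory complexes were lower in the mutant by camera, as were those of mitochondrial ribosomal proteins, ribosome biogenesis, aminoacyl-tRNA synthetases and fat synthesis. The autophagy and immune lists were higher, and of all these autophagy passed with an estimated correlation (adjusted p = 0.0164). All 12 tested complex IV genes fell (median -0.70), and 23 of 27 complex I genes did (median -0.86, n = 3 arrays per group). Muscle marker genes were lower in the same arrays, 11 of 13 of them (median -1.98).

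Of 11261 probe sets 3425 passed (30.4%), 1664 higher and 1761 lower, by limma with Benjamini-Hochberg adjustment. The arrays did not overlap for 4672, where chance gives 10%. The largest rises were in Drsl5 (6.68 ± 0.61 SE, adjusted p = 5.68e-06), the sorbitol dehydrogenase gene Sodh1 (5.61 ± 0.13 SE, 4.2e-11), Sid, which encodes a stress-induced DNase (4.60), the glucose transporter gene Glut1 (4.57 ± 0.40 SE, 4.18e-06), the ceramidase gene CDase (4.56), the cytochrome P450 gene Cyp304a1 (4.47) and 4 genes with only a CG symbol, from CG3868 (6.38) to CG10764 (4.69). The largest falls were in digestive protease genes of the Jonah family, Jon65Aiv (-9.33 ± 2.39 SE, 0.00976), Jon25Bi (-7.58) and Jon65Aiii (-7.53), the related protease gene yip7 (-7.32), LysS (-7.04) and 5 genes with only a CG symbol, among which CG42846 fell by 8.37 ± 0.28 SE (1.41e-09). Gut markers as a list had 5 lower and none higher (adjusted p = 0.132), and their mean log2 level was 5.50 to 5.55 in mutant controls and 5.70 to 8.94 in the other arrays. Without wildtype control replicate 3 the log2 change was -6.58 for Jon25Bi, -6.86 for Jon65Aiii, -6.53 for yip7, -6.19 for LysS and 7.38 for CG3868, and without wildtype control replicate 1 it was -8.18 for Jon25Bi.

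The lists of the respiratory chain and of mitochondrial gene expression were lower, while those of the TCA cycle (2 higher, 5 lower, adjusted p = 0.141) and of nuclear control of mitochondria (4 higher, 1 lower, adjusted p = 0.118) did not pass. Complex I had 24 lower adjusted over the list alone (adjusted p = 4.2e-12), complexes II and III 8 of 10, also adjusted over the list alone (median -0.76, adjusted p = 1.33e-05), complex IV 12 also adjusted over the list alone (adjusted p = 7.78e-07), and complex V 11 of 13, also adjusted over the list alone (median -1.003, adjusted p = 2.84e-08). In that order the adjusted p was 0.208, 0.208, 0.11 and 0.11 with an estimated correlation. Examples were ND-ASHI (-1.26), Cyt-c1 (-1.43), COX5B (-1.36), ATPsynCF6 (-1.71) and ATPsynC (-1.41). Of 71 mitochondrial ribosomal protein genes 61 fell and 1 rose (64 and 1 adjusted over the list alone, median -0.77, adjusted p = 1.16e-18, adjusted p = 0.208 with an estimated correlation), with mRpL20 at -1.33 and mRpS35 at -1.76. Of 20 genes of mitochondrial transcription and import 12 fell and 1 rose, likewise adjusted over the list alone (median -0.66, adjusted p = 5.18e-06, adjusted p = 0.11 with an estimated correlation), with Tom40 at -1.63, Hsp60A at -1.67 and ewg at 1.01. The log2 ratio of 3' to 5' signal of the eIF-4a control probe sets was 1.77 to 1.95 in mutant controls and 1.50 to 1.76 in wildtype controls. With it as a covariate the mean log2 difference of the 62 tested respiratory chain genes went from -0.80 ± 0.07 SE to -0.65 ± 0.07 SE. Muscle markers fell in these arrays too (camera adjusted p = 0.00173, adjusted p = 0.725 with an estimated correlation, 12 lower adjusted over the list alone), for example bt (-0.97) and Mlp84B (-2.33, or -1.69 without wildtype control replicate 3). That list ended by fry (adjusted p = 0.0614) and with the muscle score as a covariate (0.942), chosen after the data were seen. Their mean log2 level was 6.44 to 6.55 in mutant controls, 7.77 to 7.79 in wildtype control replicates 1 and 2 and 10.35 in wildtype control replicate 3.

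Of the growth lists, DNA replication did not pass (2 higher, 5 lower, adjusted p = 0.424). Ribosome biogenesis had 45 of 49 lower and 1 higher (46 and 1 adjusted over the list alone, median -1.21, adjusted p = 2.73e-18, adjusted p = 0.11 with an estimated correlation), with NHP2 at -2.11, the helicase gene pit at -2.10 and NAT1 at 0.49. Of the aminoacyl-tRNA synthetase genes 17 of 20 fell, also adjusted over the list alone (median -1.01, adjusted p = 3.36e-10, adjusted p = 0.0535 with an estimated correlation), including SerRS (-1.37) and TrpRS (-1.29). Of 39 translation factor genes 20 fell and 2 rose (22 and 2 adjusted over the list alone, median -0.42, adjusted p = 0.000162, adjusted p = 0.245 with an estimated correlation). Those that rose were eIF4E3, a cap-binding isoform (3.42), and eIF2A (0.56). Of 16 unfolded protein response and ER genes 8 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.41, adjusted p = 0.0106, adjusted p = 0.284 with an estimated correlation), with P58IPK at -1.001.

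The lists of fat synthesis and of beta-oxidation were both lower by camera. In fatty acid and triglyceride synthesis 12 of 21 fell (14 adjusted over the list alone, median -0.58, adjusted p = 0.000207, adjusted p = 0.253 with an estimated correlation), with the acyltransferase gene Agpat2 at -2.75 and malic enzyme (Men) at -2.10. In beta-oxidation 7 of 18 fell and 1 rose, likewise adjusted over the list alone (median -0.36, adjusted p = 0.00421, adjusted p = 0.29 with an estimated correlation), with Acox57D-d at -2.69, Acat1 at -0.76 and the carnitine palmitoyltransferase gene whd at 1.08.

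Autophagy genes rose: 14 of 22 were higher and 1 lower (17 and 1 adjusted over the list alone, median 0.53, adjusted p = 1.37e-06), and the list passed with an estimated correlation as well (adjusted p = 0.0164). CtsL1 rose by 1.67 and CtsB by 1.41. Of 18 immune effector genes 9 rose and 1 fell, likewise adjusted over the list alone (median 0.98, adjusted p = 0.00446, adjusted p = 0.29 with an estimated correlation), with Drsl5 and the serpin gene nec (1.35) among them. Of 20 juvenile hormone and ecdysone genes 8 rose (9 higher and 1 lower adjusted over the list alone, median 0.46, adjusted p = 0.0208, adjusted p = 0.234 with an estimated correlation), with E23 at 2.88 and MsrA at 2.28. The insulin and FOXO linked list had 8 of 19 higher and 3 lower (10 and 3 adjusted over the list alone, median 0.44, adjusted p = 0.0349, adjusted p = 0.234 with an estimated correlation). Akt rose by 1.12 and foxo by 0.91, while Lpin fell by 1.05 and scyl by 1.34. That list ended without wildtype control replicate 3 (0.0662) and with the muscle score as a covariate (0.186), a setting chosen after the data were seen. It also ended with the mean of all probe sets of a gene (0.0775).

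Mutant Inr against wildtype Inr larvae gave the effect of the mutation under InR overexpression, where fewer genes passed. In complex I 18 of 27 genes were lower (median -0.47), in the mitochondrial ribosomal list 19 of 71 (median -0.30, n = 3 arrays per group) and in ribosome biogenesis 16 of 49, while 4 of 22 autophagy genes were higher. These lists passed camera, but not with an estimated correlation (adjusted p 0.163 to 0.264). The glue genes Sgs3 and Sgs1 were higher in the mutant.

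In this comparison 1113 of 11261 probe sets passed (9.88%), 554 higher and 559 lower, by limma with Benjamini-Hochberg adjustment, and 3393 did not overlap, where chance gives 10%. The count was 631 without wildtype Inr replicate 1, and 668 without mutant Inr replicate 1 and 668 without mutant Inr replicate 2. It rose to 2198 with arrays weighted by quality. Of the changes seen between controls, 60.3% of the 554 higher here were higher there too (81.9 probe sets with independent lists, odds ratio 10.7, Fisher's exact test p = 7.89e-144) and 379 of the 559 were lower in both (87.4, odds ratio 14.2, p = 5.35e-182), and 53 passed in opposite directions. These comparisons share no array.

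The largest rises were in Sgs3 (7.74 ± 2.11 SE, adjusted p = 0.036), Jon65Aii (6.04 ± 0.41 SE, 2.39e-06), Sgs1 (5.86, 0.0355), the lysozyme gene LysX (4.46), Ama (3.59), eIF4E3 (3.40 ± 0.27 SE, 1.03e-05), the adhesion gene klg (3.31), TotZ (2.997) and 2 genes with only a CG symbol, CG3868 (3.63) and CG11842 (2.97). Sgs3 was lost without any 1 of 6 arrays, wildtype control replicate 2, wildtype Inr replicates 1 and 3 and mutant Inr replicates 1 to 3 (adjusted p 0.0524 to 0.133). Sgs1 was lost without any of these or wildtype Inr replicate 2 (0.0515 to 0.117). The rise of Sgs3 was 6.80 without wildtype Inr replicate 1 and 9.39 without wildtype Inr replicate 2, and that of Ama was 2.67 without mutant Inr replicate 2. The largest falls were in CG4408 (-7.99 ± 0.32 SE, 2.72e-08), Obp83cd (-7.20 ± 0.36 SE), CG42846 (-7.05), the cathepsin gene CtsL3 (-5.99), CG9040 (-5.89), nol (-5.19), tobi (-4.60 ± 0.51 SE, 0.000184), mat (-4.59), CG11893 (-3.86) and the neprilysin-like gene Nepl19 (-3.47). Salivary gland markers as a list were higher in the mutant, with 2 of 12 higher (7 adjusted over the list alone, median 4.07, adjusted p = 0.019, adjusted p = 0.904 with an estimated correlation), and did not pass by fry (adjusted p = 0.414).

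The mitochondrial lists were complex I (24 lower and 1 higher adjusted over the list alone, adjusted p = 1.68e-13), complexes II and III with 7 of 10 lower (8 adjusted over the list alone, median -0.51, 5.11e-07), complex IV with 5 of 12 (7 adjusted over the list alone, median -0.31, 0.000139) and complex V with 7 of 13 (10 adjusted over the list alone, median -0.35, 5.36e-06). The TCA cycle list had 7 of 14 lower and 1 higher (7 and 2 adjusted over the list alone, median -0.33, 0.000408). For each of these lists the adjusted p was 0.163 with an estimated correlation. Examples were ND-20 (-0.70), SdhD (-0.74), UQCR-Q (-0.85), ATPsynCF6 (-0.85) and the aconitase gene mAcon1 (-0.67). The mitochondrial ribosomal list had 26 lower adjusted over the list alone (adjusted p = 1.68e-13, adjusted p = 0.264 with an estimated correlation), with mRpL45 at -1.29 and mRpL55 at -0.85. Mitochondrial transcription and import had 5 of 20 lower (9 adjusted over the list alone, median -0.35, adjusted p = 1.84e-05, adjusted p = 0.163 with an estimated correlation). Its member Tom40 (-0.57) was lost without wildtype Inr replicate 1 or mutant Inr replicate 2 (0.0746 to 0.0808). Muscle markers did not differ detectably here (0 higher and 0 lower, adjusted p = 0.592).

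Ribosome biogenesis had 16 of 49 lower (19 adjusted over the list alone, median -0.47, adjusted p = 8.12e-12), with Nop60B at -0.76. Of the aminoacyl-tRNA synthetase genes 3 of 20 were lower (4 adjusted over the list alone, median -0.28, adjusted p = 0.000195), TyrRS by 0.79 on the log2 scale. Autophagy had 4 of 22 higher (6 higher and 1 lower adjusted over the list alone, median 0.29, adjusted p = 0.00289), such as Atg18a (0.62). These 3 lists had an adjusted p of 0.163 with an estimated correlation. In fatty acid synthesis 2 of 21 were lower (3 adjusted over the list alone, median -0.20, adjusted p = 0.00678, adjusted p = 0.462 with an estimated correlation), with Men at -1.57, and the list ended without wildtype Inr replicate 2 (0.0584) and by fry (adjusted p = 0.105). The insulin and FOXO linked list had 4 of 19 higher and tobi lower (5 and 1 adjusted over the list alone, median 0.28, adjusted p = 0.0273, adjusted p = 0.209 with an estimated correlation) and ended without wildtype Inr replicate 2 (0.0516) or mutant Inr replicate 2 (0.0622) and with the mean of all probe sets of a gene (0.0669). DNA replication passed as a list with no single member past the threshold, also adjusted over the list alone (median -0.32, adjusted p = 0.0251, adjusted p = 0.647 with an estimated correlation), and ended without the same arrays (0.0727 and 0.0622). It ended as well with the stricter filter (0.0516), by fry (adjusted p = 0.326) and with the muscle score as a covariate (0.0828), a setting chosen after the data were seen. Malpighian tubule markers were lower, Irk3 by 2.55 (1 of 10 lower, 2 adjusted over the list alone, median -0.94, adjusted p = 0.0308, adjusted p = 0.904 with an estimated correlation), and ended without wildtype Inr replicate 1 (0.0704 for the list and 0.0567 for Irk3) or mutant Inr replicate 3 (0.101 for the list). The Malpighian list ended with the stricter filter (0.0594) and by fry (adjusted p = 0.362) as well.

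**Figure D3:**
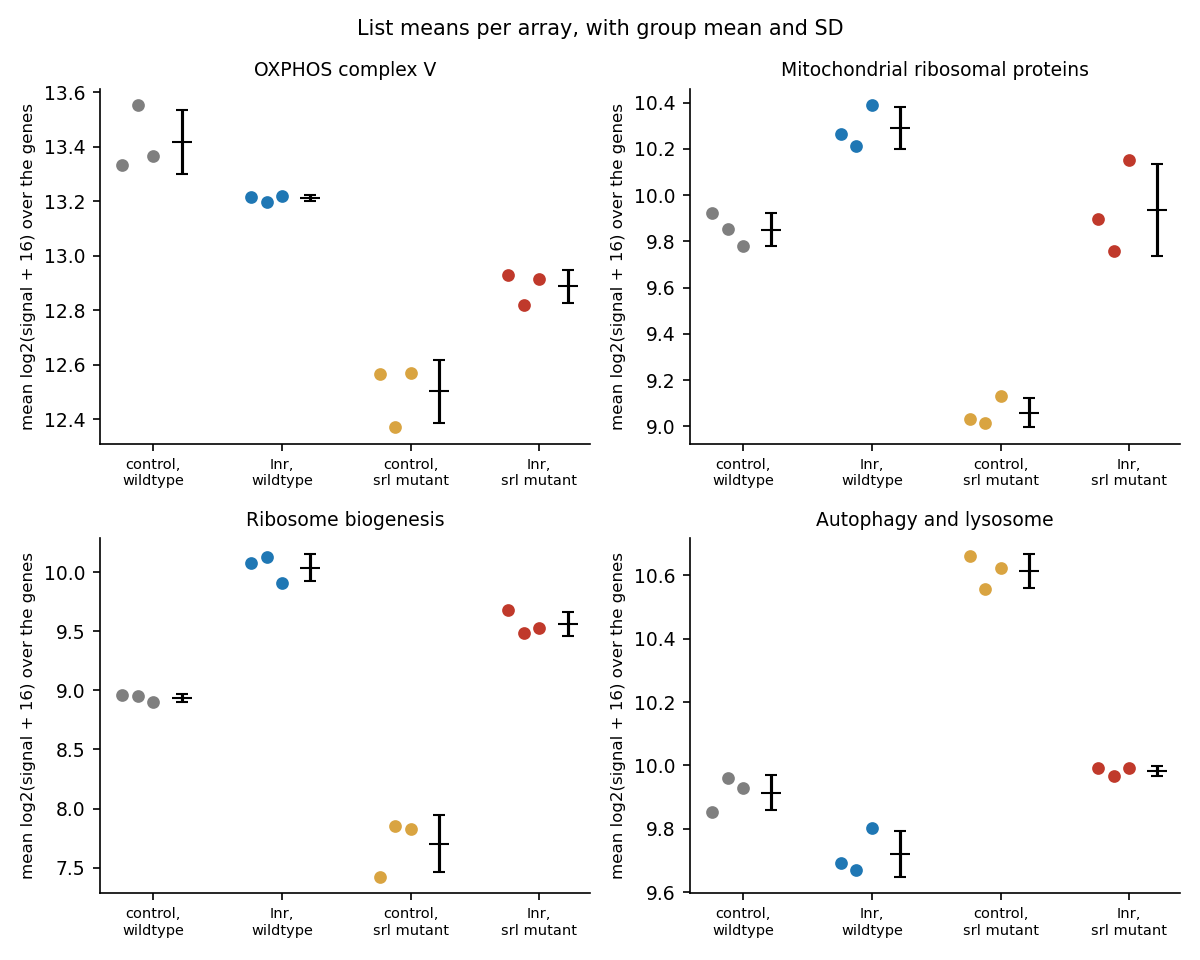
Mean log2 level of the genes of 4 lists in each of the 12 arrays (points) with the group mean and SD (bars), for complex V, mitochondrial ribosomal proteins, ribosome biogenesis, and autophagy and lysosome. Ribosome biogenesis stood at 8.94 ± 0.03 in wildtype controls, 10.04 ± 0.11 in wildtype Inr, 7.70 ± 0.24 in mutant controls and 9.56 ± 0.10 in mutant Inr larvae.

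The question of the study, whether the response to InR depends on spargel, was tested as the difference between both Inr responses, mutant minus wildtype. A more positive response in the mutant was called for 10 of 13 complex V, 3 of 12 complex IV and 4 of 27 complex I genes, 17 of 71 mitochondrial ribosomal, 19 of 49 ribosome biogenesis and 12 of 20 aminoacyl-tRNA synthetase genes. A more negative one was called for 5 of 22 autophagy genes. These 7 lists passed camera, and 0 lists passed with an estimated correlation (adjusted p 0.0968 to 0.583 for these). Complex V genes stood at a mean log2 level of 13.42 ± 0.12 (SD, n = 3) in wildtype controls and 13.21 ± 0.01 in wildtype Inr larvae, but rose from 12.50 ± 0.11 to 12.89 ± 0.06 in the mutant. Sodh1 went from 8.84 to 13.21 in the wildtype and from 14.45 to 14.14 in the mutant. The known insulin target tobi rose from 6.15 to 10.38 in the wildtype and stood at 5.90 and 5.78 in the mutant.

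By limma with Benjamini-Hochberg adjustment 1290 of 11261 probe sets passed (11.5%), 730 with a more positive response in the mutant and 560 with a more negative one. Of the 730, 336 passed only as a rise in the mutant, 190 rose in both backgrounds, 126 fell in the wildtype alone by the threshold and 44 fell in the wildtype and rose in the mutant. Of the 560, the numbers were 246 for a fall in the mutant alone by the threshold, 126 for a rise in the wildtype alone, 89 for a fall in both and 59 for a rise in the wildtype and a fall in the mutant. In 519 of the 730 the mutant controls were below wildtype controls while the Inr groups did not pass against each other, and in 412 of the 560 mutant controls were above likewise. These counts share arrays with the test of the difference, so that part of them follows from its arithmetic.

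The largest positive differences were in LysS (11.33 ± 2.23 SE, adjusted p = 0.00596), Jon65Aiii (10.46, 0.0117), Sgs3 (10.05, 0.048), yip7 (9.10), Jon25Bi (8.54), Sgs1 (8.36), Jon25Bii (5.78) and 3 genes with only a CG symbol, CG31789 (9.22), CG14302 (8.44) and CG12715 (6.67). Sgs, Jon and lysozyme genes are expressed in salivary gland and gut, and gut markers varied within groups. Their mean log2 level was 5.77, 8.47 and 6.74 in wildtype Inr replicates 1 to 3 and 8.41, 7.87 and 5.70 in mutant Inr replicates 1 to 3, and as a list they did not pass (4 higher, adjusted p = 0.0798). Salivary gland markers differed as a list (median 6.37, adjusted p = 0.000616, adjusted p = 0.82 with an estimated correlation, 2 of 12 higher and 8 adjusted over the list alone), but did not pass by fry (adjusted p = 0.178). Sgs3 was lost when any 1 of 8 arrays was left out (all but wildtype Inr replicate 2 and the mutant controls, adjusted p 0.0697 to 0.114), and Sgs1 with any 1 of 9 (all but the mutant controls, 0.0501 to 0.0652). Jon25Bi, CG14302 and Jon25Bii were lost with any 1 of 10 (all but wildtype Inr replicate 2 and mutant Inr replicate 3, adjusted p 0.0502 to 0.0966, 0.0691 to 0.116 and 0.0519 to 0.113). CG12715 was lost with any 1 of 6 (replicates 1 and 2 of the wildtype controls, 1 and 3 of the wildtype Inr larvae, and 1 and 3 of the mutant Inr larvae, 0.0515 to 0.0744).

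Sizes of these differences depended on single arrays. With 1 array left out LysS ran from 9.93 to 13.80 and yip7 from 7.998 to 11.24 (without mutant Inr replicates 1 and 3). Jon65Aiii ran from 8.30 to 12.53 and CG31789 from 7.75 to 10.83 (without wildtype Inr replicates 1 and 2), and Sgs3 from 6.71 to 11.73 and Sgs1 from 5.65 to 9.76 (without mutant control replicates 1 and 3). Jon25Bi ran from 6.87 to 10.55 and CG14302 from 6.81 to 10.71 (without wildtype Inr replicate 1 and mutant Inr replicate 3), Jon25Bii from 4.75 to 7.53 (without mutant Inr replicates 1 and 3) and CG12715 from 5.22 to 8.27 (without mutant control replicate 1 and wildtype Inr replicate 2).

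The largest negative differences were in Drsl5 (-9.28 ± 0.87 SE, 4.02e-05), Obp83cd (-4.83), CDase (-4.70), Sodh1 (-4.69 ± 0.18 SE, 2.83e-08), the P450 gene Cyp6d5 (-4.49), tobi (-4.34, 0.00218), CtsL3 (-4.29), meep (-4.13), CG30083 (-5.39) and CG6870 (-5.34). None of these was lost without any 1 array, and Drsl5 was -10.26 without mutant Inr replicate 2. Drsl5 went from 7.60 to 10.34 in the wildtype and from 14.28 to 7.74 in the mutant, in mean log2 level. Obp83cd rose from 6.90 to 12.59 in the wildtype and stood at 4.53 and 5.39 in the mutant.

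Among gene lists, complex V differed most within the respiratory chain, with 10 of 13 genes responding more in the mutant (11 adjusted over the list alone, median 0.63, adjusted p = 1.07e-06), ATPsynbeta by 0.85 and ATPsynC by 0.83. Complex IV had 3 of 12 (6 adjusted over the list alone, median 0.41, 0.000299), with COX5B at 0.90, and complex I 4 of 27 (9 adjusted over the list alone, median 0.35, 0.000299), with ND-ASHI at 0.77. With an estimated correlation the adjusted p was 0.249, 0.249 and 0.583 in that order. The list of complexes II and III did not pass (adjusted p = 0.0965, 2 higher, Cyt-c1 at 0.92). Mitochondrial ribosomal genes had 17 of 71 (24 adjusted over the list alone, median 0.46, adjusted p = 1.35e-08, adjusted p = 0.568 with an estimated correlation), with mRpL20 at 1.03 and mRpS35 at 1.14. In mitochondrial transcription and import 6 of 20 responded more (9 adjusted over the list alone, median 0.30, adjusted p = 0.00965, adjusted p = 0.485 with an estimated correlation), with Tom40 at 1.06 and the ADP/ATP carrier gene sesB at 1.01. Muscle markers differed in the same direction (median 1.45, adjusted p = 0.0048, adjusted p = 0.82 with an estimated correlation, with 1 of 13 higher, also adjusted over the list alone, bt at 1.21). The muscle list ended without wildtype control replicate 3 (0.0681), by fry (adjusted p = 0.278) and, chosen after the data were seen, without both mutant control replicate 1 and wildtype control replicate 3 (0.0545) or with the muscle score as a covariate (0.907). By fry complex I ended too (adjusted p = 0.0799). With the RNA quality ratio as a covariate, chosen after the result was seen, the mean difference over the 62 tested respiratory chain genes went from 0.40 ± 0.10 SE to 0.22 ± 0.09 SE.

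Ribosome biogenesis had 19 of 49 with a larger response in the mutant (23 adjusted over the list alone, median 0.60, adjusted p = 2.62e-10, adjusted p = 0.249 with an estimated correlation), NHP2 by 1.60 and pit by 1.43. Aminoacyl-tRNA synthetases had 12 of 20 (14 adjusted over the list alone, median 0.75, adjusted p = 2.78e-07, adjusted p = 0.132 with an estimated correlation), such as ArgRS (1.07) and SerRS (1.15). Of 39 translation factor genes 11 were more positive and 3 more negative, likewise adjusted over the list alone (median 0.23, adjusted p = 0.00711, adjusted p = 0.568 with an estimated correlation), with eIF2beta at 1.23 and eIF4G1 at 0.84. The unfolded protein response and ER list had 4 of 16 (10 adjusted over the list alone, median 0.51, adjusted p = 0.000299, adjusted p = 0.249 with an estimated correlation), P58IPK by 1.12 and TRAM by 0.75. Fatty acid synthesis had 5 of 21 (7 adjusted over the list alone, median 0.56, adjusted p = 0.0119), with Agpat2 at 2.19 and the acyltransferase gene mdy at 1.09, and beta-oxidation 2 of 18, also adjusted over the list alone (median 0.31, adjusted p = 0.0119), with Acox57D-d at 2.15. For both the adjusted p was 0.568 with an estimated correlation, and by fry fatty acid synthesis ended (adjusted p = 0.0799). Autophagy had 5 of 22 more negative and 1 more positive (6 and 1 adjusted over the list alone, median -0.43, adjusted p = 0.000483, adjusted p = 0.0968 with an estimated correlation), CtsL1 by -2.23 and CtsB by -0.91. DNA replication genes had no member with a detectable difference.

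**Figure D4:**
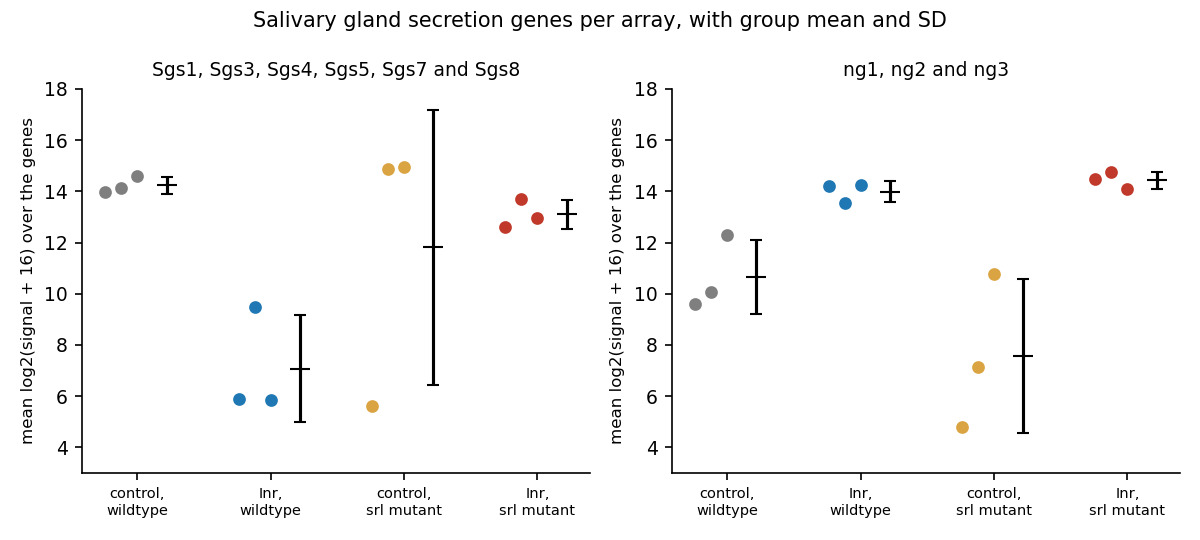
Mean log2 level of 6 Sgs glue genes and of ng1, ng2 and ng3 in each of the 12 arrays (points), with group means and SD. The Sgs genes averaged 14.23 ± 0.33 in wildtype controls and 7.07 ± 2.10 in wildtype Inr larvae, and in mutant controls replicate 1 stood at 5.602 and the other two at 14.89 and 14.94.

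Across the 5 comparisons 14, 16, 17, 15 and 14 lists passed camera with its preset correlation, in the order described. Of these calls, those of the autophagy list for the Inr effect in the mutant and for mutant against wildtype controls also held with an estimated correlation. In no called list did the median, the mean and the test differ in sign. By fry, 12, 15, 16, 11 and 10 of the called lists passed; fry tests whether a list's genes move one way on balance and does not compare them with other genes.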

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

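Results are listed here because the response to InR differed between the backgrounds by a test of that difference. In this part, the tests on the salivary glue genes and the second count of splits for the interaction, after additive effects were taken off, were chosen after the result was seen.

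The difference of responses was called for 1290 probe sets. Other splits of the arrays into groups of the same sizes gave as many in 6 of 100 splits drawn, the real one included, and the highest other split gave 4479. That split turns the Inr labels around in one background, and without it the highest was 1708, which points to the strong Inr effect as a structure of the samples, so this test does not exclude chance. After the additive effects of background and Inr were taken off each probe set, 1 of 100 splits gave as many, the real one, and the highest other gave 1. In the other splits of this second count the difference of responses adds to the spread and lowers the calls. The second count was chosen after the first was seen, so it does not exclude chance either, nor does it cover differences in dissected tissue. For the 4 comparisons of 3 against 3 arrays, the 10 splits are too few for a share under 0.05. The real split was in each the 1 split with as many calls, with 2921 against a highest other of 0 for the Inr effect in the wildtype, 3827 against 0 in the mutant, 3425 against 21 for mutant against wildtype controls and 1113 against 6 for the mutant effect with Inr.

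By list, the median difference of responses, mutant minus wildtype, was 0.35 for complex I, 0.41 for complex IV, 0.63 for complex V, 0.46 for mitochondrial ribosomal proteins, 0.30 for mitochondrial transcription and import, 0.60 for ribosome biogenesis, 0.23 for translation factors and 0.75 for aminoacyl-tRNA synthetases. It was 0.56 for fatty acid synthesis, 0.31 for beta-oxidation, 0.51 for the unfolded protein response and -0.43 for autophagy. Among tissue markers it was 6.37 for salivary gland and 1.45 for muscle. With an estimated correlation 0 of these 14 lists passed, and by fry 10 did.

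By gene, the difference was -0.88 for InR itself. It was positive for LysS (11.33), Jon65Aiii (10.46), Sgs3 (10.05), CG31789 (9.22), yip7 (9.10), Jon25Bi (8.54), CG14302 (8.44), Sgs1 (8.36), CG12715 (6.67) and Jon25Bii (5.78). It was negative for Drsl5 (-9.28), CG30083 (-5.39), CG6870 (-5.34), Obp83cd (-4.83), CDase (-4.70), Sodh1 (-4.69), Cyp6d5 (-4.49), tobi (-4.34), CtsL3 (-4.29) and meep (-4.13). The 10 positive values and that of Drsl5 moved by over 1.5-fold when 1 array was left out, LysS to 9.93 without mutant Inr replicate 1 and to 13.80 without mutant Inr replicate 3, Jon65Aiii to 8.30 without wildtype Inr replicate 1, and Sgs3 to 6.71 without mutant control replicate 1.

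The larger mutant response of the mitochondrial lists went with low control levels, since the 62 tested respiratory chain genes lay lower in mutant than in wildtype controls by a mean log2 difference of -0.80 ± 0.07 SE. Muscle carried over at dissection could give such a difference, because muscle markers were low in mutant controls, but with the muscle score as a covariate the difference was -0.79 (SE 0.11), which argues against it as the whole cause. RNA quality was read from the 3' to 5' ratio of the eIF-4a control probe sets alone. With it the difference was -0.65 (SE 0.07), which argues against quality by this ratio as the whole cause of the control difference. The rise of the respiratory chain genes with InR in the mutant was 0.47 (SE 0.07) by groups alone and 0.24 (SE 0.08) with the eIF-4a ratio. The difference of responses was 0.40 (SE 0.10) and 0.22 (SE 0.09), in fits chosen after the results were seen. Another GAPDH control pair ran the other way, with ratios of 12.7 to 22.0 in mutant controls, 26.7 to 30.7 in wildtype controls and 20.3 to 27.8 in mutant Inr larvae. An Act5C pair had 2.64 to 3.95, 2.16 to 2.62 and 3.66 to 3.89 in that order. RNA quality stays open as a cause of part of both effects. Age stays open, as 0 backgrounds were sampled at more than 1 age, and age and genotype cannot be told apart. An effect of spargel on these genes is therefore one of the hypotheses left.

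Glue genes differed between the groups in opposite ways. Less salivary gland tissue in wildtype Inr samples would lower all its genes alike, but ng1 to ng3 rose there on average by 3.34 (SE 0.86) while the 6 Sgs genes changed by -7.16 (SE 1.22), which argues against it as the whole cause. The gland gene sage fell there by 2.34 (SE 0.72), so less gland stays open as a part of it. Sgs3, an abundant member, had a mean log2 level of 14.58 in wildtype controls, and the list shares no gene with another list. In mutant control replicate 1, 11 of 12 salivary markers were lower by over 1 (log2) than in the other two mutant controls. That array was singled out by these same markers, so this count does not tell less gland in the sample from another stage. Developmental stage stays open, as 0 groups were sampled at more than 1 age. Hormone response genes differed between groups of the same age too. The juvenile hormone and ecdysone list had a mean log2 level of 7.92 in wildtype controls and 7.36 in wildtype Inr larvae. In mutant controls it was 8.50 and in mutant Inr larvae 7.62. These values cannot tell a shift of stage from an effect of InR on the hormone genes themselves.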

How the results depend on the processing

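The fits without 2 arrays and with the muscle score were chosen after the data were seen. Across all alternatives, results of named genes, mostly chosen for passing, kept their side of the threshold in 10342 cases. They lost it in 763, gained it in 3, and reversed from past it in 0. Of the 10342, 3 that did not pass changed sign. For lists the numbers were 1840, 133, 0 and 3. With a minimum of 2-fold the 5 counts were 1260, 1812, 1467, 383 and 757, in the order of the report, and the shared responses 506 higher and 238 lower, by construction. With array weights the mutant effect with Inr gave 2198 calls, and the cause was not tested. With an estimated correlation 0, 1, 1, 0 and 0 lists passed, since correlated genes then count for less. Cytosolic ribosomal proteins reversed for the Inr effect in the wildtype with quantile normalization (median 0.0155), and the cause was not tested. With the muscle score as covariate the median of muscle markers turned positive without Inr (0.0608), and in the interaction it shrank to 0.0890 while the direction of the test turned, by construction.

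Leaving out 1 array gave 2309 to 2948 calls for the Inr effect in the wildtype and 3210 to 3971 in the mutant. Mutant against wildtype controls gave 2824 to 3431, the mutant effect with Inr gave 631 to 1255 and the interaction 892 to 1357. Shared responses were 877 to 1045 and 708 to 808, the gain in response size 0.18 to 0.26, and called lists 11 to 15, 14 to 17, 17 to 19, 13 to 19 and 14 to 16. A group left with 2 arrays takes its spread from the pooled fit.

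Without both doubted arrays (mutant control replicate 1 and wildtype control replicate 3) the 5 counts were 2838, 3593, 3228, 1385 and 1295, and with the muscle score 2904, 3384, 2466, 1218 and 1065. With the replicate number as a block they were 3061, 3997, 3531, 1240 and 1389. Whether the numbers pair the samples stayed open: 3 of 18 correlations of same-numbered deviations were over 0.1 (-0.11 to 0.20). Of the 12 arrays, 7 correlated best with their own number, out of 3 numbers. Each count with the block was higher than in the main fit (2921, 3827, 3425, 1113 and 1290). A fit of only the compared groups does not exist for the interaction and was not run, and the 2-fold minimum was not applied to lists or response size. Near background the pseudocount makes a change look smaller than it is.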

Other observations

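In this part, genes outside the named lists were chosen after their values were seen, while the tests on chromosome position were written down before their results. Adjusted p-values are from limma with Benjamini-Hochberg adjustment.

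The 5 tested Turandot genes, which encode secreted stress peptides, rose with InR in both backgrounds. TotB rose by 4.95 in the wildtype and 6.74 in the mutant (difference 1.78, adjusted p = 0.0089), TotZ by 3.58 and 5.79 (difference 2.20, 0.0046), and TotC by 6.15 and 4.94 (difference -1.20, 0.114). The antifungal peptide gene Drs was higher in mutant than in wildtype controls by 3.68 (0.0036), like its relative Drsl5 (6.68). The small heat shock genes Hsp26 and Hsp27 were higher there by 3.38 ± 0.79 SE (0.0053) and 2.93 (0.0071), and Hsp27 fell by 4.08 with InR in the mutant (log2 change -4.90 without mutant Inr replicate 2 and -3.33 without mutant Inr replicate 1). The heat shock list did not pass in mutant against wildtype controls (3 higher and 2 lower, adjusted p = 0.479), nor with InR (adjusted p = 0.614 and 0.629).

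Of 95 tested P450 and glutathione transferase genes 23 rose and 31 fell with InR in the wildtype (list adjusted p = 0.432) and 24 rose and 29 fell in the mutant (0.629). Cyp6a23 rose by 2.34 and 3.87, Cyp4d8 by 3.62 and 2.54, while GstE3 fell by 2.46 and 2.96. GstD2 was lower in the mutant by 4.33 without and 3.11 with Inr on the log2 scale (-4.33 and -3.11). Both collagen IV genes, which fat body and blood cells make, rose with InR, Col4a1 by 1.62 and 1.79 and vkg by 1.09 and 1.98. The blood cell marker Hml was lower in the mutant (-2.42 and -2.54), but the list of blood cell markers did not pass without InR (1 higher and 5 lower, adjusted p = 0.163) or with it (0 higher and 1 lower, adjusted p = 0.592). Of the yolk protein genes, which adult females express, Yp1 rose by 4.80 ± 0.98 SE in the wildtype (0.00266) and did not pass in the mutant (1.07, 0.454), Yp2 rose by 4.00 and 3.38, whereas Yp3 fell by 1.33 and 0.67. The fall of Yp3 in the mutant was lost without mutant control replicate 1 or 2 or mutant Inr replicate 1 or 2 (adjusted p up to 0.128). The sex-determination gene dsx fell by 0.72 and 0.68. Of the other check genes for sex, Sxl (-0.52 and -0.39) and msl-2 (0.61 and 0.03) passed in neither background. The gene tra did not pass in the wildtype (-0.10, 0.645) and fell in the mutant (-0.42, 0.0311). The sex of the larvae was not given in the sources used here.

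Some genes stood low or high in the mutant whether or not InR was overexpressed. By at least 4-fold in both comparisons, 23 genes with a known chromosome were low and 10 high, such as CG42846 (-8.37 and -7.05) and eIF4E3 (3.42 and 3.40). Neighbours of srl carried along with the mutation could give this pattern, but among the 200 genes on each side of srl lay 2 of the 23 against 1.98% of tested genes (one-sided Fisher's exact p = 0.0750, odds ratio interval 0.537 to 19.8), and 0 of the 10 (p = 1), too few to decide. The 2 neighbours were Obp83cd and flip. By the same one-sided Fisher's exact test, on the chromosome that carries srl lay 18 of the 23 (78.3% against 44.7%, p = 0.00108) and 8 of the 10 (80%, p = 0.0260), where 41.7% of 115 genes higher and 24.4% of 41 genes lower with InR by at least 4-fold in both backgrounds lay there. This is consistent with variants of the mutant stock's chromosome as the source of part of these differences, a hypothesis that a line with the same chromosome and a functional srl gene would be needed to test, and effects of srl or age on single genes stay open.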
